A study of Mus musculus with 7 samples.

How the data were processed

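The samples were 7 mouse liver RNA libraries, 3 from the PBS group and 4 from the PTH group, assigned from the treatment label. Per the file headers, the deposited table gives FPKM and a count for each gene and library. The sample labels name Bowtie 0.12.2 and the build mm8, and the quantifier is not given in the sources used here. The gene positions in the table match GRCm38 instead: of the 21839 genes with an identifier in GENCODE M21 (96.8%), 95.0% have a locus that spans the M21 gene within 5000 bases, and 36.7% have the same start and end. Coordinates in the text are those of M21. The count columns deposited by the authors are a scaled signal: between 92.4% and 94.2% of the values in a library (those above 0.5 of its step) are whole multiples, within 0.05, of a step that differs between libraries. They were therefore treated as scaled values and no count test was run. Totals divided by the step, taken as 1 read, gave the estimated reads per library. The locus span that the table lists per gene, deposited as length, was not used in a test. One line of the table names no gene. The loci of 5877 genes (26.1%) are also listed for another gene, and 79 symbols stand on more than 1 line.

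Genes with at least 0.5 FPKM in at least 3 libraries were kept, and log2(FPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust), with Benjamini-Hochberg adjustment and a two-sided threshold of 0.05. The values were not rescaled. A fold on this scale understates the change of low genes. The design planned a count test if the table held counts and this test for FPKM. The 41 gene lists, with 1595 different members, were compared with all other tested genes by camera with a preset correlation of 0.01, and again with an estimated correlation and by fry. The choices of test, lists, alternatives and named genes were made before the data were examined, except where stated. Genes were named by rule: 14 genes of the question, the 10 largest rises and 10 largest falls among genes past the threshold with groups that do not overlap and a mean of at least 1 FPKM in the higher group, leaving out predicted genes, and the 4 smallest p in each described list. The described lists were those past camera and 8 more, of which xenobiotic enzymes, fatty acid oxidation and clock genes were picked after seeing the data. Other lists are given by counts. Some genes that the rule names are not reported here.

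Exact two-sided permutation tests used SciPy 1.17.1, and figures matplotlib 3.10.9 under Python 3.11.15. On simulated data with the spread of these libraries and 11861 genes, the fit recovered 4 of 93 genes changed by 1 log2 unit (4.3%) and 66 of 107 changed by 2 (61.7%), with 2 false calls. A smaller part of the genes was changed there than passed in the data, which makes the adjusted threshold stricter, so these rates do not carry over to the data. Camera called the 1 list that was shifted and 0 of 40 unchanged lists, with genes simulated independently of each other.

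Alternatives tried were leaving out each library, the replicate number as a block, quantile and common-median scaling, no filter, a minimum of 1 FPKM, pseudocounts of 0.1 and 1, limma without trend and robust, array weights, an adjusted p of 0.1, and a log2 change of at least 1. Added after seeing the data were the scaled counts with a pseudocount and minimum of 5, leaving out shared loci, removing each library's trend with transcript length and GC content (splines of 4 degrees of freedom), common-median scaling with each library left out, scaling without the 50 most abundant genes, the permutation of lists, and symbol families of at least 10 genes. A comparison with calls by the authors was planned and is not analysed here.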

Results

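RNA was sequenced from livers of C57BL/6 mice given parathyroid hormone (PTH), a peptide hormone that acts through the receptor encoded by Pth1r and raises cyclic AMP, or phosphate-buffered saline (PBS). There were 3 PBS and 4 PTH libraries, named here by group and replicate, such as PTH 2. The sample titles shorten the groups to C and C+P, and the labels used here do not say what C stands for, so it is open whether all mice also had another treatment and whether PBS livers were healthy or injured. The deposited table lists 22564 genes in FPKM, of which 21092 have a protein-coding transcript in GENCODE M21. Its estimated reads came to 2556673, 1734534 and 1200680 in PBS 1 to 3 and 3222687, 3281505, 2546786 and 1621721 in PTH 1 to 4, from the listed genes alone. The Pearson correlation across genes of log2 values, for which genes are not independent replicates, ran from 0.891 to 0.924 within PBS, 0.875 to 0.945 within PTH and 0.799 to 0.889 between the groups. The first principal component held 50.3% of the variance and placed the 3 PBS libraries apart from the 4 PTH libraries. The labels name mice but do not state that each library is a separate animal, so p-values measure the spread between these samples.

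The series has one comparison, PTH against PBS, which was used to ask whether Crebl2 and genes of liver fibrosis differ between these livers. The labels name no change of the receptor, so signalling through Pth1r was not tested. The acute phase gene Saa2, whose product livers make in inflammation, fell from 12883 ± 1278 in PBS to 1834 ± 932 in PTH. Bhmt, a gene of amino acid breakdown, fell with 466 ± 168 in PBS and 44.7 ± 50.9 in PTH, and the neutrophil gene S100a9 fell with 149.7 ± 172 in PBS and 4.59 ± 5.46 in PTH. The ribosomal protein gene Rpl30 (shared locus) rose with 25.8 ± 11 in PBS and 143 ± 22.6 in PTH, and Fth1, a target of the oxidative stress regulator NRF2, rose with 506 ± 167 in PBS and 3213 ± 811 in PTH. Pth1r, Crebl2, Acta2, Col1a1, Col1a2 and Col3a1 did not pass the test. Values are mean ± SD of FPKM over 3 PBS and 4 PTH libraries unless library values are listed, and changes are on the log2(FPKM + 0.5) scale.

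By limma with Benjamini-Hochberg adjustment, 2990 of 11861 tested genes changed, 2709 higher and 281 lower in PTH (90.6% higher). The median change of all tested genes was 0.549. With each library scaled to a common median, 1008 genes changed, 385 higher and 623 lower (38.2% higher), and 665 of these were called in the same direction as deposited. With 1 library left out, 1445 genes changed without PBS 2, 1444 without PBS 3, 1089 without PTH 2 and 1773 without PTH 3, and the number lower was 144 without PBS 1, 159 without PBS 2, 119 without PTH 2 and 431 without PTH 1. The groups did not overlap for 4283 tested genes as deposited (36.1%, against 5.71% by chance). The all-gene shift can add to this share, which was not computed under a common median. A shared locus below marks a gene whose locus in the table is also another gene's, so that reads could be split between them. Genes said to rise or fall passed an adjusted p of 0.05.

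**Figure D1:**
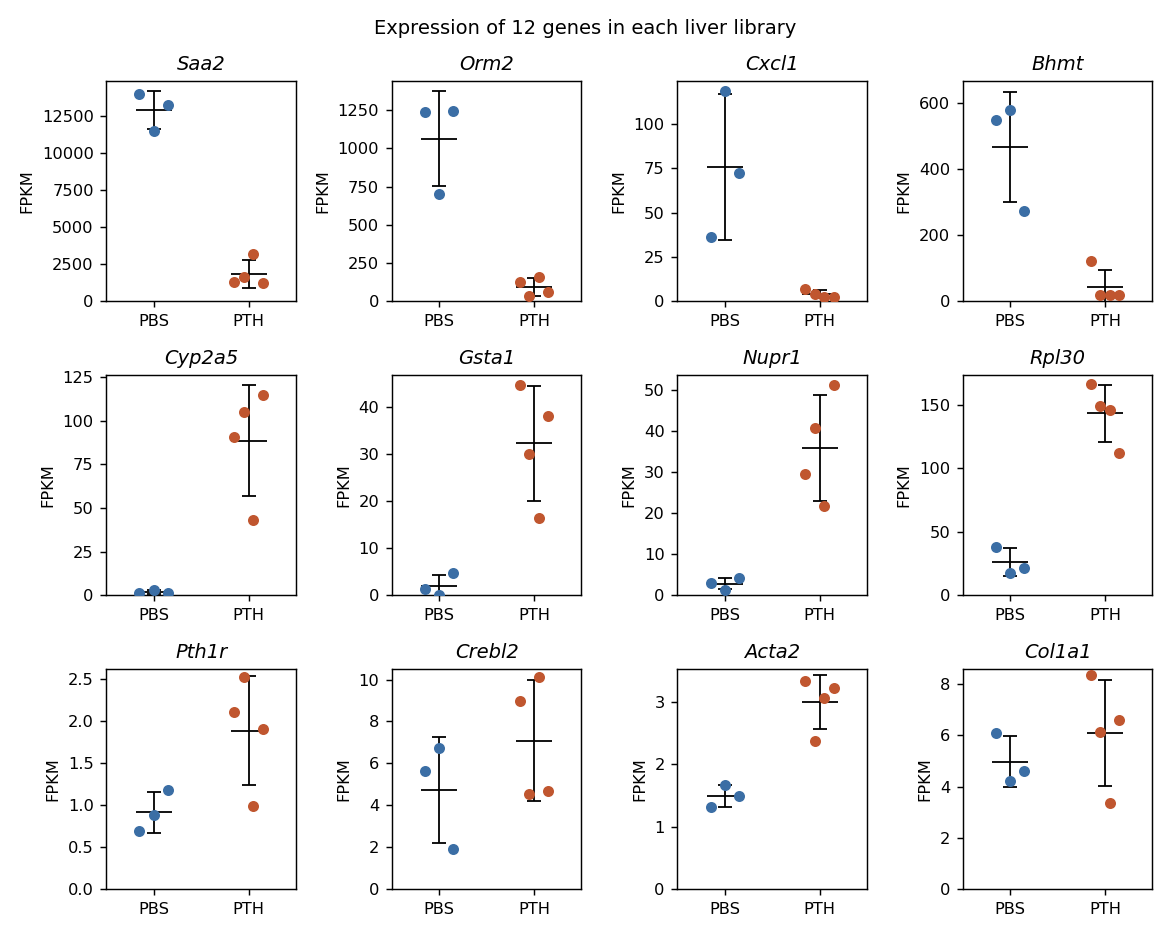
FPKM of 12 genes in each library, with 3 PBS (blue) and 4 PTH (orange) points per gene, the mean as a horizontal line and 1 SD as the error bar, each panel on its own linear axis from 0. Saa2 lay at 12883 ± 1278 in PBS and 1834 ± 932 in PTH, while the groups of Crebl2 and Col1a1 overlapped.

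The receptor gene Pth1r, on chromosome 9 from 110722085 to 110747145 (GRCm38, GENCODE M21), had library values of 0.686, 0.874 and 1.17 FPKM in PBS and 2.11, 2.52, 0.984 and 1.90 FPKM in PTH. Its log2 change was 0.72 (SE 0.36, limma adjusted p = 0.152), with an exact two-sided permutation p of 0.114. Crebl2, on chromosome 6 from 134830154 to 134858931 and a relative of the CREB transcription factors, had 5.63, 6.71 and 1.89 FPKM in PBS and 8.98, 4.53, 10.1 and 4.69 FPKM in PTH. The log2 change of Crebl2 was 0.60 (SE 0.44, limma adjusted p = 0.317), with an exact two-sided permutation p of 0.343. The change ran from 0.106 without PBS 3 to 0.902 without PBS 2. This permutation test doubles the smaller tail, so 0.0571 (2 of 35 splits) is its smallest possible p. Under a common median the changes of Pth1r and Crebl2 were 0.15 and 0.02. With scaled counts they were 0.75 (limma adjusted p = 0.131) and 0.88 (limma adjusted p = 0.0667), so Crebl2 came nearer the threshold there. Among PBS libraries Crebl2 was highest in PBS 2 by FPKM but in PBS 1 by scaled counts. The hormone gene Pth was listed at 0 in all 7 libraries, and Pthlh was listed at 0 except for 0.156 FPKM in PTH 3.

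Of 46 tested genes of the PTH receptor, cyclic AMP pathway and CREB family, 11 rose and 2 fell (14 and 2 adjusted over the list alone, 1 and 2 under a common median, 14 and 2 with scaled counts). For PTH receptor, cAMP pathway and CREB family, leaving out 1 library gave 3 rises without PTH 2, 5 rises without PBS 3, 6 rises without PBS 2, and 0 falls without PBS 1 or PBS 2 or PTH 2, 1 fall without PBS 3 or PTH 3 or PTH 4. This list did not differ from the other genes (camera adjusted p = 0.686, adjusted p = 0.868 with an estimated correlation, fry adjusted p = 0.0211 up against no change). Creb1 rose, with 1.51 ± 0.408 in PBS and 4.47 ± 0.713 in PTH, log2 change 1.31 (SE 0.31, limma adjusted p = 0.0147, not past the threshold under a common median), past the threshold in 15 of 19 alternatives, with a limma adjusted p of 0.0519 without PBS 3 and 0.0521 without PTH 2. Crem rose, with 9 ± 1.16 in PBS and 39.8 ± 11.5 in PTH, log2 change 2.04 (SE 0.30), and encodes a cyclic AMP-responsive transcription factor. Crebzf rose, with 5.29 ± 2.50 in PBS and 19.2 ± 5.70 in PTH, log2 change 1.83 (SE 0.38, not past the threshold under a common median), past the threshold in 17 of 19 alternatives. Of 40 cyclic AMP-responsive and immediate early genes, 7 fell and 3 rose (7 and 3 adjusted over the list alone, 8 and 1 under a common median, 7 and 3 with scaled counts). For cAMP-responsive and immediate early genes, leaving out 1 library gave 1 rise without PBS 3 or PTH 3, 7 rises without PTH 1. The immediate early list lay below other genes (camera adjusted p = 6.82e-07, adjusted p = 0.406 with an estimated correlation), and 11 of its genes, 4 of those that fell among them, are also handling stress genes, a list that lay below other genes too (adjusted p = 0.271 with an estimated correlation). Gadd45a fell, with 26.9 ± 3.97 in PBS and 7.03 ± 1.88 in PTH, log2 change -1.89 (SE 0.28).

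Genes of fibrosis are given by list, and a gene that did not pass the test is not shown to be unchanged. Of 42 fibrillar collagen and other matrix genes, 5 rose and 2 fell (3 and 2 adjusted over the list alone, 1 and 2 under a common median, 7 and 2 with scaled counts). For fibrillar collagens and other matrix genes, leaving out 1 library gave 2 rises without PBS 1 or PBS 3 or PTH 2 or PTH 3 or PTH 4, 3 rises without PBS 2, and 0 falls without PBS 1 or PBS 2 or PTH 2. The matrix list did not pass (camera adjusted p = 0.0777, adjusted p = 0.54 with an estimated correlation). Col1a1 did not pass the test, with 4.98 ± 0.989 in PBS and 6.11 ± 2.07 in PTH, log2 change 0.22 (SE 0.33, limma adjusted p = 0.633), from 0.063 to 0.463 with 1 library left out. Col1a2 did not pass the test, with 5.40 ± 1.78 in PBS and 6.19 ± 1.51 in PTH, log2 change 0.20 (SE 0.32, limma adjusted p = 0.659), from 0.001 to 0.425 with 1 library left out. Col3a1 did not pass the test, with 11.1 ± 3.37 in PBS and 9.74 ± 2.24 in PTH, log2 change -0.16 (SE 0.30, limma adjusted p = 0.711), from -0.416 to 0.022 with 1 library left out. Under a common median Col1a1 and Col1a2 had the other sign, at -0.35 and -0.38. Nid1 rose, with 8.06 ± 2.14 in PBS and 27.5 ± 6.06 in PTH, log2 change 1.72 (SE 0.29). Fn1 (shared locus) fell, with 462 ± 48.3 in PBS and 201 ± 81 in PTH, log2 change -1.29 (SE 0.34), past the threshold in 15 of 18 alternatives, with a limma adjusted p of 0.0543 without PBS 1, 0.0539 without PBS 2 and 0.0671 without PTH 2, and encodes fibronectin. Of 31 hepatic stellate cell and myofibroblast markers, 4 rose and 0 fell (3 and 0 adjusted over the list alone, 2 and 2 under a common median, 6 and 0 with scaled counts). Stellate cell markers did not differ from other genes (camera adjusted p = 0.857, adjusted p = 0.884 with an estimated correlation, fry adjusted p = 0.0211 up against no change). Acta2 (shared locus) did not pass the test, with 1.49 ± 0.178 in PBS and 2.99 ± 0.432 in PTH, log2 change 0.81 (SE 0.30, limma adjusted p = 0.07). Pdgfrb did not pass the test, with 2.19 ± 0.375 in PBS and 4.58 ± 1.10 in PTH, log2 change 0.90 (SE 0.31, limma adjusted p = 0.052), past the threshold in 7 of 19 alternatives, with a limma adjusted p of 0.0414 without PTH 1. Des did not pass the test, with 1.02 ± 0.485 in PBS and 1.94 ± 0.306 in PTH, log2 change 0.73 (SE 0.35, limma adjusted p = 0.143), past the threshold in 1 of 19 alternatives, from 0.429 to 0.903 with 1 library left out. Vim did not pass the test, with 19.7 ± 13.1 in PBS and 18.1 ± 4.06 in PTH, log2 change 0.03 (SE 0.38, limma adjusted p = 0.954), from -0.308 to 0.526 with 1 library left out, with the other sign (-0.54) under a common median. Tagln (shared locus) rose, with 1.24 ± 0.566 in PBS and 6.45 ± 1.33 in PTH, log2 change 2.02 (SE 0.33). Tpm1 rose, with 19.2 ± 2.03 in PBS and 66.2 ± 21.2 in PTH, log2 change 1.71 (SE 0.29). Of 28 TGF-beta pathway genes, 10 rose and 0 fell (13 and 0 adjusted over the list alone, 1 and 0 under a common median, 16 and 0 with scaled counts). For TGF-beta pathway, leaving out 1 library gave 6 rises without PTH 2. The pathway as a list missed the threshold (camera adjusted p = 0.0654, adjusted p = 0.575 with an estimated correlation, fry adjusted p = 0.0211 up against no change). Tgfb1 did not pass the test, with 3.46 ± 0.170 in PBS and 6.02 ± 1.47 in PTH, log2 change 0.69 (SE 0.30, limma adjusted p = 0.103). Id1 rose, with 3.53 ± 2.28 in PBS and 43.2 ± 18.5 in PTH, log2 change 3.51 (SE 0.47). Smad7 rose, with 2.18 ± 0.795 in PBS and 9.48 ± 3.45 in PTH, log2 change 1.87 (SE 0.37, not past the threshold under a common median), past the threshold in 18 of 19 alternatives, and encodes an inhibitor of TGF-beta signalling. Of 30 matrix-degrading enzymes and their inhibitors, 6 rose and 0 fell (6 and 0 adjusted over the list alone, 1 and 2 under a common median, 8 and 1 with scaled counts). For matrix-degrading enzymes and their inhibitors, leaving out 1 library gave 1 rise without PTH 2, 3 rises without PBS 3, and 1 fall without PTH 1. This list did not differ from other genes (camera adjusted p = 0.84, adjusted p = 0.899 with an estimated correlation, fry adjusted p = 0.0314 up against no change). Mmp12 (shared locus) rose, with 3.51, 0.316 and 0 in PBS and 10.7 ± 3.29 in PTH, log2 change 3.20 (SE 0.60). Timp1 (shared locus) did not pass the test, with 1.04, 0 and 0.598 in PBS and 1.23 ± 0.318 in PTH, log2 change 0.85 (SE 0.42, limma adjusted p = 0.15), from 0.392 to 1.205 with 1 library left out. Under a common median the log2 changes of Acta2, Pdgfrb, Des, Tgfb1 and Timp1 shrank to 0.24, 0.33, 0.15, 0.12 and 0.28.

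Of 45 acute phase genes, 24 fell and 1 rose (30 and 1 adjusted over the list alone, 31 and 0 under a common median, 23 and 1 with scaled counts). For acute phase proteins, leaving out 1 library gave 0 rises without PBS 1 or PBS 3 or PTH 1 or PTH 2 or PTH 4, and 15 falls without PTH 2. Acute phase genes lay below other genes, with a median -1.77 from the all-gene median (camera adjusted p = 8.78e-34, adjusted p = 0.271 with an estimated correlation, fry adjusted p = 0.0211 down against no change). Orm2 (shared locus) fell, with 1063 ± 311 in PBS and 95.4 ± 58.4 in PTH, log2 change -3.66 (SE 0.48). Saa4 fell, with 116 ± 16.8 in PBS and 17.8 ± 5.71 in PTH, log2 change -2.72 (SE 0.29). Steap4 fell, with 197 ± 39.8 in PBS and 24.4 ± 11.8 in PTH, log2 change -3.07 (SE 0.34). Of 21 neutrophil markers, 6 fell and 0 rose (6 and 0 adjusted over the list alone, 7 and 0 under a common median, 4 and 2 with scaled counts). Neutrophil markers lay below other genes (camera adjusted p = 1.94e-08, adjusted p = 0.374 with an estimated correlation). S100a9 fell, with 149.7 ± 172 in PBS and 4.59 ± 5.46 in PTH, log2 change -4.64 (SE 0.85). Lcn2 fell, with 1614 ± 429 in PBS and 367 ± 273 in PTH, log2 change -2.44 (SE 0.55), and is also made by hepatocytes. Prtn3 (shared locus) fell, with 21.7 ± 17 in PBS and 1.35, 0, 1.08 and 0 in PTH, log2 change -4.04 (SE 0.75). Of 42 macrophage and Kupffer cell markers, 11 fell and 4 rose (13 and 4 adjusted over the list alone, 17 and 1 under a common median, 12 and 5 with scaled counts). For macrophage and Kupffer cell markers, leaving out 1 library gave 5 falls without PBS 1 or PTH 2 or PTH 3, 6 falls without PBS 2 or PBS 3. As a list these lay below other genes (camera adjusted p = 2.46e-12, adjusted p = 0.374 with an estimated correlation). Clec4f fell, with 34.7 ± 13.8 in PBS and 9.84 ± 2.11 in PTH, log2 change -1.70 (SE 0.34), and marks Kupffer cells, the resident macrophages of the liver. Cd163 fell, with 9.60 ± 2.75 in PBS and 2.35 ± 1.08 in PTH, log2 change -1.86 (SE 0.37), and encodes a scavenger receptor. Slc40a1 rose, with 17.5 ± 1.12 in PBS and 50.9 ± 13.9 in PTH, log2 change 1.47 (SE 0.28, not past the threshold under a common median), past the threshold in 17 of 19 alternatives, and encodes the iron exporter ferroportin. Of 37 chemokine, cytokine and adhesion genes, 3 fell and 2 rose (3 and 1 adjusted over the list alone, 5 and 0 under a common median, 5 and 4 with scaled counts). For chemokines, cytokines and adhesion molecules, leaving out 1 library gave 0 rises without PBS 2 or PBS 3 or PTH 3 or PTH 4, 1 rise without PTH 2, and 5 falls without PBS 2. Chemokine genes lay below other genes (camera adjusted p = 0.0192, adjusted p = 0.374 with an estimated correlation, camera adjusted p = 0.127 under a common median). Cxcl1 fell, with 75.7 ± 41.2 in PBS and 4.04 ± 2.17 in PTH, log2 change -4.02 (SE 0.44), and encodes a neutrophil attractant. Il18 fell, with 3.88 ± 1.30 in PBS and 1.11, 1.07, 0 and 0 in PTH, log2 change -2.25 (SE 0.51). Handling stress genes, fixed in advance as a sign of tissue and RNA handling, moved with these groups. Of 14 RNA degradation and handling stress genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone, 6 and 0 under a common median, 6 and 0 with scaled counts). Their median lay -1.81 from the all-gene median (camera adjusted p = 1.47e-13, adjusted p = 0.271 with an estimated correlation, fry adjusted p = 0.0388 down against no change). Hspa1b fell, with 78.9 ± 23.7 in PBS and 12.1 ± 3.17 in PTH, log2 change -2.65 (SE 0.30). Btg2 fell, with 54.5 ± 44 in PBS and 5.05 ± 1.83 in PTH, log2 change -3.07 (SE 0.47).

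Of 46 urea cycle and amino acid breakdown genes, 13 fell and 0 rose (14 and 0 adjusted over the list alone, 21 and 0 under a common median, 13 and 0 with scaled counts). For urea cycle and amino acid breakdown, leaving out 1 library gave 1 rise without PTH 4, and 3 falls without PTH 2, 4 falls without PBS 1, 7 falls without PBS 2 or PBS 3 or PTH 4, 22 falls without PTH 1. The list lay below other genes (camera adjusted p = 7.33e-21, adjusted p = 0.406 with an estimated correlation). Bhmt fell, with 466 ± 168 in PBS and 44.7 ± 50.9 in PTH, log2 change -3.84 (SE 0.59), and encodes betaine-homocysteine methyltransferase. Sds (shared locus) fell, with 236 ± 118 in PBS and 25.5 ± 15.1 in PTH, log2 change -3.27 (SE 0.47), and encodes serine dehydratase. Asl fell, with 109.8 ± 38.7 in PBS and 31.3 ± 14.8 in PTH, log2 change -1.86 (SE 0.38), and encodes the urea cycle enzyme argininosuccinate lyase. Of 37 gluconeogenesis and glycogen genes, 9 fell and 3 rose (9 and 3 adjusted over the list alone, 11 and 2 under a common median, 7 and 3 with scaled counts). For gluconeogenesis and glycogen metabolism, leaving out 1 library gave 3 falls without PTH 2, 5 falls without PBS 1. Gluconeogenesis genes lay below other genes (camera adjusted p = 2.30e-07, adjusted p = 0.412 with an estimated correlation). Igfbp1 fell, with 442 ± 102 in PBS and 49.1 ± 26 in PTH, log2 change -3.26 (SE 0.36). Ugp2 rose, with 22.1 ± 6.69 in PBS and 124 ± 33.2 in PTH, log2 change 2.46 (SE 0.30), and encodes an enzyme that makes UDP-glucose. Of 27 cholesterol synthesis genes, 2 fell and 0 rose (1 and 0 adjusted over the list alone, 3 and 0 under a common median, 1 and 0 with scaled counts). For cholesterol synthesis, leaving out 1 library gave 1 rise without PTH 1, 2 rises without PBS 2, and 0 falls without PBS 2 or PTH 2 or PTH 3, 1 fall without PBS 1 or PTH 4, 6 falls without PTH 1. Cholesterol synthesis genes lay below other genes (camera adjusted p = 3.65e-07, adjusted p = 0.516 with an estimated correlation). Nsdhl did not pass the test, with 15.2 ± 9.33 in PBS and 5.18 ± 7.17 in PTH, log2 change -1.99 (SE 0.72, limma adjusted p = 0.0628), past the threshold in 2 of 19 alternatives, with a limma adjusted p of 0.00426 without PTH 1. Of 35 bile acid synthesis and transport genes, 5 fell and 3 rose (5 and 3 adjusted over the list alone, 7 and 0 under a common median, 5 and 4 with scaled counts). For bile acid synthesis and transport, leaving out 1 library gave 0 rises without PBS 3, 1 rise without PTH 2 or PTH 3, and 2 falls without PBS 2, 3 falls without PBS 1 or PTH 3, 8 falls without PTH 1. Bile acid genes lay below other genes (camera adjusted p = 8.65e-07, adjusted p = 0.475 with an estimated correlation). Cyp8b1 fell, with 9.14 ± 5.67 in PBS and 1.57, 0.429, 0 and 0.685 in PTH, log2 change -2.97 (SE 0.58), and encodes the enzyme for cholic acid synthesis. Slco1b2 fell, with 72.9 ± 9.29 in PBS and 23.1 ± 8.24 in PTH, log2 change -1.70 (SE 0.31), and encodes a bile acid uptake transporter. Abcb11 fell, with 50.8 ± 11.8 in PBS and 22.6 ± 4.54 in PTH, log2 change -1.15 (SE 0.27), past the threshold in 18 of 19 alternatives, with a limma adjusted p of 0.0581 without PBS 2, and encodes the bile salt export pump. Of 32 fatty acid and triglyceride synthesis genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, 2 and 3 under a common median, 5 and 3 with scaled counts). For fatty acid and triglyceride synthesis, leaving out 1 library gave 1 fall without PBS 1 or PBS 2 or PTH 2 or PTH 3 or PTH 4, 5 falls without PTH 1. Lipid synthesis genes lay below other genes (camera adjusted p = 0.00509, adjusted p = 0.532 with an estimated correlation). Lpin1 fell, with 52.7 ± 32.8 in PBS and 7.63 ± 2.19 in PTH, log2 change -2.59 (SE 0.38). Cidec rose, with 1.48, 0 and 2.53 in PBS and 15.8 ± 10.6 in PTH, log2 change 3.27 (SE 0.62), and encodes a lipid droplet protein. Of 49 fatty acid oxidation genes and PPAR-alpha targets, 8 rose and 0 fell (7 and 0 adjusted over the list alone, 4 and 4 under a common median, 8 and 0 with scaled counts). For fatty acid oxidation and PPAR-alpha targets, leaving out 1 library gave 5 rises without PBS 1 or PBS 3 or PTH 2 or PTH 3, and 1 fall without PBS 3, 4 falls without PTH 1. These did not pass as a list (camera adjusted p = 0.0664, adjusted p = 0.866 with an estimated correlation). Cyp4a10 rose, with 2.95 ± 2.47 in PBS and 47.7 ± 42.1 in PTH, log2 change 3.87 (SE 0.71). Plin2 rose, with 135 ± 45.8 in PBS and 431 ± 98.8 in PTH, log2 change 1.68 (SE 0.31).

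**Figure D2:**
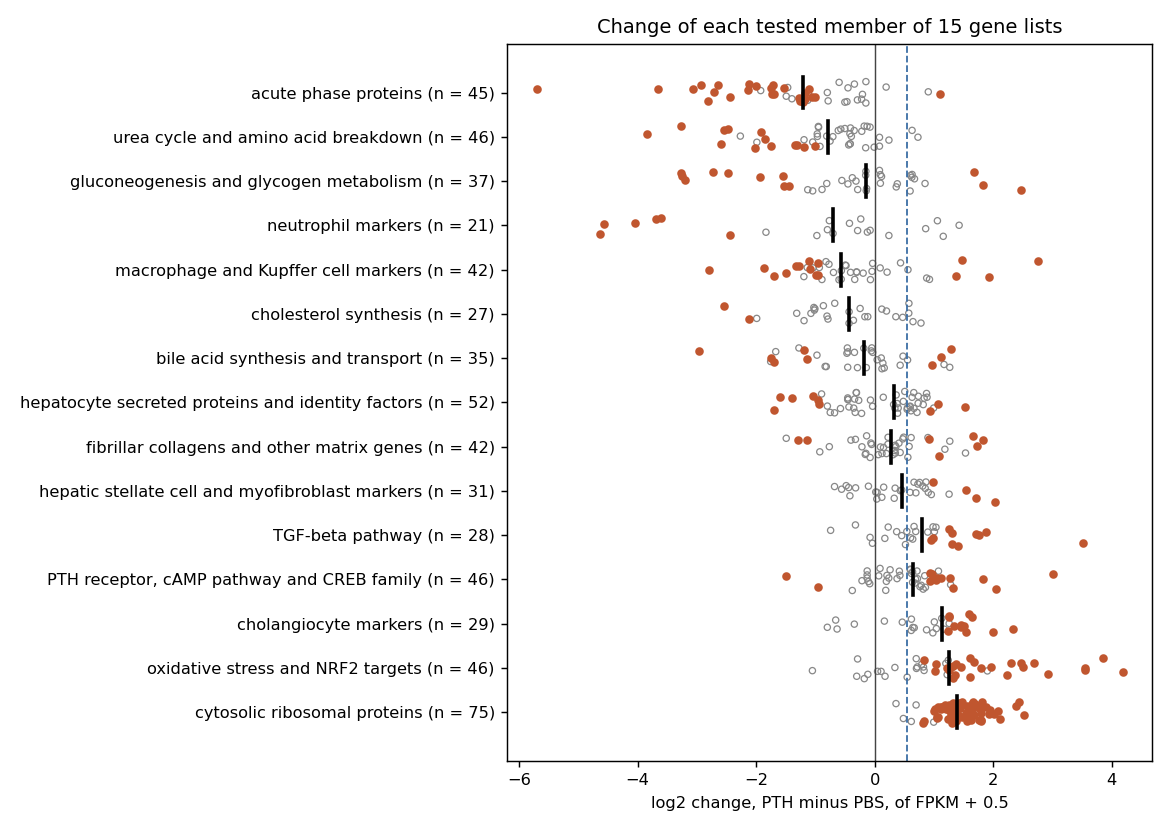
Log2 change (PTH minus PBS, FPKM + 0.5) of each tested member of 15 gene lists, with filled points past an adjusted p of 0.05, open points not past it, black bars at each list's median, a solid line at 0 and a dashed line at the all-gene median of 0.549. Of the acute phase genes 24 of 45 fell, and of the ribosomal protein genes 70 of 75 rose, or 29 under a common median.

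Of 52 hepatocyte secreted proteins and identity factors, 6 fell and 3 rose (6 and 3 adjusted over the list alone, 15 and 0 under a common median, 7 and 6 with scaled counts). For hepatocyte secreted proteins and identity factors, leaving out 1 library gave 0 rises without PBS 3 or PTH 2, 1 rise without PBS 2, and 1 fall without PTH 2, 2 falls without PBS 2, 3 falls without PBS 1 or PTH 4. The list lay below other genes (camera adjusted p = 0.000545, adjusted p = 0.6 with an estimated correlation). F7 fell, with 25.7 ± 3.69 in PBS and 9.64 ± 2.99 in PTH, log2 change -1.40 (SE 0.28). Serpinf2 fell, with 273 ± 86.2 in PBS and 93 ± 43.8 in PTH, log2 change -1.60 (SE 0.37), past the threshold in 18 of 19 alternatives, with a limma adjusted p of 0.0509 without PTH 2. Of 35 periportal hepatocyte markers, 10 fell and 5 rose (12 and 5 adjusted over the list alone, 16 and 1 under a common median, 9 and 4 with scaled counts). For periportal hepatocyte markers, leaving out 1 library gave 1 rise without PBS 3, 2 rises without PBS 2 or PTH 2 or PTH 3, 3 rises without PTH 1, and 3 falls without PTH 2, 4 falls without PBS 1, 5 falls without PBS 2, 6 falls without PBS 3 or PTH 4. Periportal markers lay below other genes (camera adjusted p = 1.32e-08, adjusted p = 0.406 with an estimated correlation). Cdh1 rose, with 10.6 ± 0.435 in PBS and 51.1 ± 11 in PTH, log2 change 2.19 (SE 0.26), and encodes E-cadherin. Aldh1b1 fell, with 20.9 ± 9.29 in PBS and 5.07 ± 3.63 in PTH, log2 change -2.02 (SE 0.47), past the threshold in 17 of 19 alternatives, with a limma adjusted p of 0.0535 without PBS 2 and 0.0521 without PTH 2. Of 31 pericentral hepatocyte markers, 6 rose and 6 fell (6 and 7 adjusted over the list alone, 1 and 9 under a common median, 7 and 7 with scaled counts). For pericentral hepatocyte markers, leaving out 1 library gave 3 rises without PTH 2. Pericentral markers lay below other genes (camera adjusted p = 0.000563, adjusted p = 0.475 with an estimated correlation). Cyp2a5 rose, with 1.86 ± 1.07 in PBS and 88.5 ± 31.9 in PTH, log2 change 5.23 (SE 0.39). Glul (shared locus) fell, with 49.6 ± 16.1 in PBS and 14.7 ± 3.89 in PTH, log2 change -1.71 (SE 0.31), and encodes glutamine synthetase. Of 48 xenobiotic cytochrome P450 and conjugating enzymes, 14 rose and 5 fell (16 and 6 adjusted over the list alone, 4 and 7 under a common median, 14 and 7 with scaled counts). For xenobiotic cytochrome P450s and conjugating enzymes, leaving out 1 library gave 8 rises without PBS 3 or PTH 2, and 2 falls without PBS 2, 3 falls without PBS 1 or PBS 3. This list did not differ from other genes (camera adjusted p = 0.385, adjusted p = 0.868 with an estimated correlation), and camera pointed down although its median lay 0.06 from the all-gene median. Ugt2b5 rose, with 42.5 ± 4.44 in PBS and 248 ± 46.9 in PTH, log2 change 2.51 (SE 0.26). Ugt2b35 rose, with 11.7 ± 4.59 in PBS and 75.7 ± 22.4 in PTH, log2 change 2.68 (SE 0.34).

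Of 75 cytosolic ribosomal protein genes, 70 rose and 0 fell (71 and 0 adjusted over the list alone, 29 and 0 under a common median, 70 and 0 with scaled counts). For cytosolic ribosomal proteins, leaving out 1 library gave 45 rises without PTH 2, 46 rises without PBS 2. Their median lay 0.83 from the all-gene median (camera adjusted p = 2.25e-14, adjusted p = 0.516 with an estimated correlation, fry adjusted p = 0.0211 up against no change). Rps26 rose, with 71.6 ± 14.4 in PBS and 275 ± 46.4 in PTH, log2 change 1.94 (SE 0.26). Rps27 rose, with 27.4 ± 14.5 in PBS and 139 ± 31.9 in PTH, log2 change 2.44 (SE 0.38). Of 46 oxidative stress genes and NRF2 targets, 26 rose and 0 fell (31 and 0 adjusted over the list alone, 14 and 1 under a common median, 27 and 0 with scaled counts). For oxidative stress and NRF2 targets, leaving out 1 library gave 1 fall without PTH 1. NRF2 targets lay above other genes (camera adjusted p = 0.000119, adjusted p = 0.505 with an estimated correlation, fry adjusted p = 0.0211 up against no change). Fth1 rose, with 506 ± 167 in PBS and 3213 ± 811 in PTH, log2 change 2.69 (SE 0.33), and encodes ferritin heavy chain. Ugdh rose, with 33.7 ± 10.3 in PBS and 185 ± 33.2 in PTH, log2 change 2.47 (SE 0.28). Ephx1 rose, with 24.3 ± 9.55 in PBS and 133 ± 18.9 in PTH, log2 change 2.51 (SE 0.32). Of 64 nuclear genes of the respiratory chain, 20 rose and 0 fell (22 and 0 adjusted over the list alone, 2 and 0 under a common median, 23 and 0 with scaled counts). For respiratory chain genes encoded in the nucleus, leaving out 1 library gave 4 rises without PTH 2, 6 rises without PBS 2 or PBS 3, 8 rises without PTH 3. Respiratory chain genes lay above other genes (camera adjusted p = 0.023, adjusted p = 0.866 with an estimated correlation, camera adjusted p = 0.0681 under a common median). Ndufb9 rose, with 34.6 ± 12.5 in PBS and 123 ± 17.2 in PTH, log2 change 1.87 (SE 0.28). Of 12 mitochondrially encoded transcripts, 0 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 1 under a common median, 0 and 0 with scaled counts). These lay below other genes (camera adjusted p = 0.000745, adjusted p = 0.532 with an estimated correlation). mt-Co3 (shared locus) did not pass the test, with 49.8 ± 15 in PBS and 33.3 ± 11.9 in PTH, log2 change -0.60 (SE 0.35, limma adjusted p = 0.207), past the threshold in 2 of 18 alternatives, from -0.850 to -0.345 with 1 library left out.

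Of 29 cholangiocyte markers, 12 rose and 0 fell (13 and 0 adjusted over the list alone, 2 and 2 under a common median, 13 and 0 with scaled counts). For cholangiocyte markers, leaving out 1 library gave 5 rises without PTH 2, 6 rises without PBS 3. Markers of bile duct cells lay above other genes (camera adjusted p = 0.0495, adjusted p = 0.54 with an estimated correlation, fry adjusted p = 0.0211 up against no change). Anxa5 (shared locus) rose, with 24.7 ± 6.50 in PBS and 126 ± 28.6 in PTH, log2 change 2.33 (SE 0.29). Krt8 rose, with 216 ± 59 in PBS and 716 ± 343 in PTH, log2 change 1.65 (SE 0.37, not past the threshold under a common median), past the threshold in 18 of 19 alternatives, and is also expressed by hepatocytes. Of 40 cell cycle genes, 4 rose and 2 fell (2 and 2 adjusted over the list alone, 1 and 9 under a common median, 7 and 2 with scaled counts). For cell cycle genes, leaving out 1 library gave 1 rise without PBS 2 or PTH 2, 2 rises without PTH 4, and 0 falls without PBS 1 or PTH 2. Cell cycle genes lay below other genes (camera adjusted p = 0.000395, adjusted p = 0.556 with an estimated correlation). Pcna rose, with 3.24 ± 2.03 in PBS and 19.7 ± 4.01 in PTH, log2 change 2.57 (SE 0.38). Mki67 fell, with 3.52 ± 3.34 in PBS and 0.439 ± 0.268 in PTH, log2 change -1.83 (SE 0.49), past the threshold in 16 of 19 alternatives, with a limma adjusted p of 0.0644 without PBS 1, 0.0748 without PTH 2 and 0.051 without PTH 3. Of 32 p53 targets and growth arrest genes, 6 rose and 4 fell (6 and 4 adjusted over the list alone, 1 and 5 under a common median, 9 and 4 with scaled counts). For p53 targets and growth arrest genes, leaving out 1 library gave 2 rises without PTH 2, 3 rises without PBS 2, and 2 falls without PBS 2. As a list these lay below other genes (camera adjusted p = 0.0276, adjusted p = 0.527 with an estimated correlation, camera adjusted p = 0.0982 under a common median). Bax rose, with 6.50 ± 1.78 in PBS and 25.9 ± 6.36 in PTH, log2 change 1.92 (SE 0.30). Plk3 (shared locus) fell, with 70.5 ± 24 in PBS and 13.5 ± 12.1 in PTH, log2 change -2.60 (SE 0.50). Of 42 unfolded protein and integrated stress response genes, 3 fell and 2 rose (1 and 1 adjusted over the list alone, 3 and 1 under a common median, 3 and 5 with scaled counts). For unfolded protein and integrated stress response, leaving out 1 library gave 1 rise without PBS 1 or PBS 2 or PTH 2, 4 rises without PTH 1, and 1 fall without PBS 1 or PTH 2, 5 falls without PTH 1. The list lay below other genes (camera adjusted p = 0.023, adjusted p = 0.575 with an estimated correlation, camera adjusted p = 0.111 under a common median). Nupr1 rose, with 2.81 ± 1.44 in PBS and 35.8 ± 12.9 in PTH, log2 change 3.48 (SE 0.38). Atf3 (shared locus) fell, with 104 ± 31.4 in PBS and 23.5 ± 6.97 in PTH, log2 change -2.13 (SE 0.32). Of 26 heat shock genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone, 0 and 5 under a common median, 5 and 4 with scaled counts). For heat shock genes, leaving out 1 library gave 1 rise without PBS 3. Heat shock genes lay below other genes (camera adjusted p = 0.00197, adjusted p = 0.475 with an estimated correlation), and 2 of them, Hspa1a and Hspa1b, which both fell, are also handling stress genes. Dnajb1 fell, with 51.3 ± 22.5 in PBS and 12 ± 2.55 in PTH, log2 change -1.99 (SE 0.32). Hspa9 rose, with 64.3 ± 9.87 in PBS and 152 ± 22.7 in PTH, log2 change 1.24 (SE 0.25, not past the threshold under a common median), past the threshold in 18 of 19 alternatives. Of 24 dendritic cell and MHC class II genes, 1 rose and 1 fell (1 and 0 adjusted over the list alone, 0 and 3 under a common median, 3 and 1 with scaled counts). For dendritic cell and MHC class II genes, leaving out 1 library gave 0 rises without PBS 2 or PTH 2, and 0 falls without PBS 1 or PBS 2 or PBS 3 or PTH 2 or PTH 3 or PTH 4, 3 falls without PTH 1. Dendritic cell genes lay below other genes (camera adjusted p = 0.0192, adjusted p = 0.406 with an estimated correlation). Fscn1 rose, with 0.556 ± 0.0761 in PBS and 2.37 ± 0.746 in PTH, log2 change 1.40 (SE 0.35, not past the threshold under a common median), past the threshold in 15 of 19 alternatives, with a limma adjusted p of 0.0544 without PBS 2 and 0.0599 without PTH 2. Naaa fell, with 2.60 ± 0.540 in PBS and 1 ± 0.310 in PTH, log2 change -1.06 (SE 0.34), past the threshold in 11 of 19 alternatives, with a limma adjusted p of 0.0596 without PBS 1, 0.0879 without PBS 2, 0.124 without PBS 3, 0.0947 without PTH 2, 0.0737 without PTH 3 and 0.0803 without PTH 4. Of 9 T and NK cell markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone, 0 and 0 under a common median, 1 and 0 with scaled counts). The tested T and NK cell markers lay below other genes (camera adjusted p = 0.023, adjusted p = 0.374 with an estimated correlation, camera adjusted p = 0.101 under a common median). The list has 46 members, and only 3 were tested at a minimum of 1 FPKM or with scaled counts. That call thus rests on few genes, most of them at low values, and does not show a loss of these cells. Tcf7 (shared locus) rose, with 1.03 ± 0.267 in PBS and 3.47 ± 0.435 in PTH, log2 change 1.39 (SE 0.31, not past the threshold under a common median), past the threshold in 16 of 18 alternatives.

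Of 28 circadian clock genes, 6 rose and 2 fell (7 and 3 adjusted over the list alone, 1 and 3 under a common median, 8 and 4 with scaled counts). For circadian clock genes, leaving out 1 library gave 1 rise without PBS 2, 2 rises without PBS 3, 3 rises without PTH 2 or PTH 3. Clock genes did not differ from other genes as a list (camera adjusted p = 0.505, adjusted p = 0.866 with an estimated correlation). Dbp (shared locus) rose, with 1.84 ± 2.23 in PBS and 12.8 ± 5.55 in PTH, log2 change 2.82 (SE 0.55). Nfil3 fell, with 23.7 ± 3.30 in PBS and 6.98 ± 2.89 in PTH, log2 change -1.76 (SE 0.31). Of 54 interferon-stimulated genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone, 0 and 1 under a common median, 14 and 0 with scaled counts). For interferon-stimulated genes, leaving out 1 library gave 2 rises without PTH 2, 3 rises without PBS 3, 4 rises without PBS 1, 27 rises without PTH 3. Interferon genes missed the threshold (camera adjusted p = 0.0993, adjusted p = 0.867 with an estimated correlation, camera adjusted p = 0.0138 under a common median). Of 9 B and plasma cell markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 0 under a common median, 0 and 0 with scaled counts). For B and plasma cell markers, leaving out 1 library gave 1 rise without PBS 1. B cell markers did not pass (camera adjusted p = 0.137, adjusted p = 0.516 with an estimated correlation). Of 31 vitamin D, calcium and phosphate genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, 1 and 2 under a common median, 8 and 0 with scaled counts). Mineral genes did not pass (camera adjusted p = 0.252, adjusted p = 0.575 with an estimated correlation). Of 42 sinusoidal and other endothelial markers, 7 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 1 under a common median, 14 and 0 with scaled counts). For sinusoidal and other endothelial markers, leaving out 1 library gave 0 rises without PTH 2, 1 rise without PBS 2 or PBS 3, 2 rises without PTH 3, 4 rises without PBS 1. Endothelial markers did not pass (camera adjusted p = 0.486, adjusted p = 0.867 with an estimated correlation, fry adjusted p = 0.0301 up against no change). Of 23 genes higher in male livers, 9 rose and 4 fell (10 and 5 adjusted over the list alone, 3 and 5 under a common median, 9 and 3 with scaled counts). For sex-biased liver genes, higher in males, leaving out 1 library gave 4 rises without PBS 3, and 2 falls without PBS 1 or PBS 2 or PTH 2 or PTH 3. Male-biased genes did not pass (camera adjusted p = 0.494, adjusted p = 0.867 with an estimated correlation), and camera pointed down although their median lay 0.49 from the all-gene median. Of 18 genes higher in female livers, 7 rose and 0 fell (8 and 1 adjusted over the list alone, 1 and 0 under a common median, 6 and 0 with scaled counts). For sex-biased liver genes, higher in females, leaving out 1 library gave 2 rises without PBS 2 or PTH 2, and 1 fall without PTH 1. Female-biased genes did not pass (camera adjusted p = 0.569, adjusted p = 0.867 with an estimated correlation). Of 16 erythroid cell markers, 4 rose and 0 fell (4 and 0 adjusted over the list alone, 0 and 1 under a common median, 3 and 0 with scaled counts). For erythroid cell markers, leaving out 1 library gave 0 rises without PBS 2 or PTH 2, 1 rise without PBS 3, 2 rises without PBS 1 or PTH 1 or PTH 3. Erythroid markers did not pass (camera adjusted p = 0.857, adjusted p = 0.941 with an estimated correlation), with camera pointing up and a median -0.04 from the all-gene median. Of 7 mesothelial, adipocyte, pancreatic and muscle markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone, 1 and 0 under a common median, 1 and 0 with scaled counts). For mesothelial, adipocyte, pancreatic and muscle markers, leaving out 1 library gave 1 rise without PBS 3 or PTH 1 or PTH 2 or PTH 3 or PTH 4. Markers of neighbouring tissues did not pass (camera adjusted p = 0.947, adjusted p = 0.953 with an estimated correlation), with camera pointing up and a median -0.21 from the all-gene median.

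Of the 41 lists, 25 passed camera with its preset correlation, 4 up and 21 down, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.271. With the preset correlation, the other 34 splits of the libraries into 3 and 4 gave a median of 16 lists, from 7 to 25. By fry, which tests a list against no change and not against other genes, and so takes in the all-gene shift, 10 lists passed in one direction, 8 up and 2 down, and 37 in either direction. An exact permutation of each list's mean difference, added after seeing the data, counted the splits with an absolute difference as large, so its smallest possible p is 0.0286 (1 of 35). By it 12 lists reached that p, with an adjusted p of 0.0976, so no list passed 0.05 after adjustment. Some lists called by camera were far from that p. Cholesterol synthesis, cell cycle and respiratory chain genes each had 7 of 35 splits as large (permutation p = 0.2). Unfolded protein and integrated stress response genes had 12 of 35 (permutation p = 0.343).

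Among genes with the largest changes, Mup18 rose, with 45.4, 108 and 0 in PBS and 438 ± 86.2 in PTH, log2 change 4.99 (SE 1.55, limma adjusted p = 0.0458, not past the threshold under a common median), past the threshold in 8 of 19 alternatives, with a limma adjusted p of 0.154 without PTH 1, 0.0892 without PTH 2, 0.11 without PTH 3 and 0.0939 without PTH 4, and a log2 change of 2.61 without PBS 3, and encodes a major urinary protein. Reads of Mup genes and of the Gsta genes could be split between near-identical copies. Gsta1 rose, with 1.36, 0 and 4.62 in PBS and 32.2 ± 12.2 in PTH, log2 change 4.19 (SE 0.64, limma adjusted p = 0.00373). Gsta4 rose, with 3.81 ± 3.35 in PBS and 63 ± 44.4 in PTH, log2 change 3.84 (SE 0.60). Gsta2 rose, with 1.19, 2.30 and 0 in PBS and 16.2 ± 6.79 in PTH, log2 change 3.55 (SE 0.54). Cbr3 was listed at 0 in all 3 PBS libraries and 3.97, 11.4, 1.78 and 9.10 in PTH (limma adjusted p = 0.00344). Nrg1 rose, with 1.82, 0 and 0.622 in PBS and 12.4 ± 5.55 in PTH, log2 change 3.42 (SE 0.55, limma adjusted p = 0.00386). A2m was listed at 89.1, 2.86 and 58.1 in PBS and 0 in all 4 PTH libraries (limma adjusted p = 0.00373). B3galt1 fell, with 67.4 ± 15.4 in PBS and 2.72 ± 2.19 in PTH, log2 change -4.67 (SE 0.52, limma adjusted p = 0.00145). Scara5 fell, with 12.5 ± 3.47 in PBS and 0.593, 0.0634, 0.496 and 0 in PTH, log2 change -4.10 (SE 0.39, limma adjusted p = 0.0012), and encodes a ferritin receptor. Ngp fell, with 21.1 ± 31.9 in PBS and 0, 0.182, 0 and 0 in PTH, log2 change -3.69 (SE 0.98, limma adjusted p = 0.0224), past the threshold in 11 of 17 alternatives, with a limma adjusted p of 0.0531 without PBS 3, 0.0678 without PTH 1, 0.0606 without PTH 2, 0.0658 without PTH 3 and 0.0563 without PTH 4, and a log2 change of -2.16 without PBS 1, and encodes a neutrophil granule protein. Eif4ebp3 (shared locus) fell, with 48.4 ± 42.1 in PBS and 2.11 ± 0.589 in PTH, log2 change -3.64 (SE 0.67, limma adjusted p = 0.00649).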

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

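The tests over splits of the libraries, of scaling, of the clock arms and of handling stress and of the spread of acute phase genes were chosen after the results were seen, while the bounds for the tests of depth and of transcript length and GC content were written before. In 12 of the 142 named genes tested for it, 1 of the 4 PTH libraries lay far from the rest on the log2 scale. The measure was the gap to the nearest library over the range of the 4, with 1 cutoff for all genes. That cutoff was not adjusted for the 142 genes, so some of the 12 can arise by chance. A single gene listed here therefore does not show that a library is unusual. For Pthlh, Ngp, Mpo and Aurkb the other PTH values are 0, so any value above 0 stands out and says little. Pthlh was highest in PTH 3, at 0.156 FPKM against 0 in the other PTH libraries. Bhmt was highest in PTH 1, at 121 FPKM against 18.3 to 19.8 in the others. Ngp was highest in PTH 2, at 0.182 FPKM against 0 in the other PTH libraries. Eif4ebp3 was lowest in PTH 1, at 1.24 FPKM against 2.33 to 2.48 in the others. Mpo was highest in PTH 4, at 0.136 FPKM against 0 in the other PTH libraries. Aurkb was highest in PTH 3, at 0.493 FPKM against 0 in the other PTH libraries. F10 was highest in PTH 1, at 73.7 FPKM against 55.6 to 58 in the others. mt-Nd3 was lowest in PTH 4, at 3.25 FPKM against 14.7 to 18.1 in the others. mt-Nd4l was highest in PTH 1, at 49.5 FPKM against 24.4 to 26.1 in the others. Dnajb1 was highest in PTH 2, at 15.8 FPKM against 10.3 to 10.9 in the others. Cox7a2 was lowest in PTH 4, at 56.2 FPKM against 77.6 to 82 in the others. Tcf7 was lowest in PTH 3, at 2.82 FPKM against 3.64 to 3.72 in the others.

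Of the 35 splits of the 7 libraries into 3 and 4, 1 gave as many as 2990 genes, the real one. That share, 0.0286, is the smallest that 35 splits can give, and the test was chosen after the result was seen. It argues against chance for the gene count but does not exclude it. The highest other split gave 398 genes and set PTH 2, PTH 3 and PTH 4 against PTH 1 and the PBS libraries. Under a common median the same split gave 669 genes against 1008 for the real one, so PTH 1 stands apart from the other PTH libraries. For the 25 lists called by camera, 2 of the 35 splits gave as many, the highest other 25, so chance cannot be excluded for that count. In the other 34 splits camera called a median of 16 lists, from 7 to 25. A call by camera with its preset correlation is thus weak evidence that a list differs.

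Most changed genes were higher in PTH livers, with an all-gene median of 0.549. Scaling to the FPKM total without the 50 most abundant genes brought the median to 0.196, with 742 genes higher and 455 lower. Scaling to the whole FPKM total left it at 0.489. The 50 most abundant genes of each library, not always those left out, took 51.1% to 52.3% of PBS and 36% to 40.5% of PTH values. A general rise of the remaining genes would lower the median under the first scaling too. That scaling therefore cannot tell such a rise from an effect of abundant transcripts. Saa1 and Saa2 alone, Saa1 chosen after its values were seen, held 7.31% to 9.37% in PBS and 0.78% to 2.24% in PTH. Lower depth with loss of low genes is argued against, since the 3956 genes with a mean of at least 10 FPKM had a median of 0.618. A general rise in transcripts after PTH was not tested apart from these.

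Of 75 ribosomal protein genes, 70 rose in PTH livers (camera adjusted p = 0.516 with an estimated correlation). After each library's trend with transcript length and GC content was removed, their median stayed 0.773 above the all-gene median and 70 of 75 rose, which argues against that trend as the whole cause. The number that rose was 45 without PTH 2 and 46 without PBS 2, and 29 under a common median. PTH treatment stays open as an untested explanation.

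Of 45 acute phase genes, 24 fell in PTH livers and 1 rose (15 fell without PTH 2, and 0 rose without PBS 1, PBS 3, PTH 1, PTH 2 or PTH 4; camera adjusted p = 0.271 with an estimated correlation). Their median lay -1.767 from the all-gene median, with an SD of 1.208 over the members, which argues against scaling, since 1 factor per library moves all genes alike. The median handling stress gene lay -1.808 from the all-gene median, so handling stress of the PBS livers is not excluded. It cannot be told apart from treatment, since these genes are not a sign of handling alone. Of the 14 handling stress genes 11 are also in the cyclic AMP-responsive list, of which 4 fell and 0 rose, so these lists do not give separate evidence. A difference in time of day at collection cannot be told apart from treatment, since the Dbp arm of the clock moved against the Arntl arm by 1.647, and 2 of the 35 splits were as large (highest other 1.674). PTH treatment itself also stays open, and the labels used here give no time of collection.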

How the results depend on the processing

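The alternatives with scaled counts, shared loci, length and GC content, and a common median with a library left out were chosen after seeing the data. As deposited, 2990 genes changed (2709 higher, 281 lower), and leaving out 1 library gave 1089 (PTH 2) to 3141 (PTH 1) genes, 970 to 2710 higher and 119 to 431 lower. Quantile normalization gave 977 (467 higher, 510 lower) and a common median 1008 (385 and 623). A common median with 1 library left out gave 267 (96 and 171) without PBS 1, 449 (157 and 292) without PBS 2, 489 (180 and 309) without PBS 3, 1685 (644 and 1041) without PTH 1, 272 (69 and 203) without PTH 2, 487 (134 and 353) without PTH 3 and 458 (133 and 325) without PTH 4. The higher share of calls and their number thus depend on scaling and on single libraries, and the cause was not tested. An adjusted p of 0.1 gave 464 genes lower, as a looser threshold must. Same-numbered libraries did not deviate together (correlations -0.031, -0.156 and 0.010), while pairs with different numbers ran from -0.198 to 0.215. These values give no sign that numbers pair the libraries, but cannot exclude it. The replicate block gave 1735 genes (1558 higher, 177 lower), and as PTH 4 has no partner there, it drops out of that comparison. Filter, pseudocount, trend, array weights, scaled counts, shared loci, and length and GC settings gave 2136 to 4051 genes. Of the 25 lists called by camera, 0 passed with an estimated correlation. By fry, which tests against no change and not against other genes, 10 lists passed (8 up, 2 down), so that count answers another question. Pth1r and Crebl2 passed the threshold under no alternative. Pth1r turned to -0.056 under a common median without PBS 1, and Crebl2 to -0.393, -0.091 and -0.173 without PBS 3, PTH 1 and PTH 3. Under quantile normalization and a common median, Col1a1 turned to -0.344 and -0.348, Col1a2 to -0.381 and -0.376, and Vim to -0.509 and -0.539. Under array weights Col1a1 turned to -0.020 and Vim to -0.211, and under the block Vim to -0.019 and mt-Nd3 to 0.032. With 1 library left out, Col3a1 ran from -0.416 to 0.022, Vim from -0.308 to 0.526 and mt-Nd3 from -0.792 to 0.032. The lists given next did not pass camera and changed sign in their mean against other genes. Fatty acid oxidation gave 0.139 under the block, 0.013 with no filter and -0.256 to 0.139 with 1 library left out. Xenobiotic enzymes gave -0.013 at 1 FPKM, -0.020 at a pseudocount of 0.1, -0.055 with array weights, -0.002 with scaled counts and -0.139 to 0.124 with 1 library left out. Clock genes gave 0.069 with no filter, the PTH and CREB list -0.003 with scaled counts, and matrix enzymes -0.020 with scaled counts and -0.030 without shared loci. Stellate markers gave 0.003 with quantile normalization, 0.031 with no filter and -0.072 to 0.005 with 1 library left out. Over the alternatives, for the named genes other than Pth1r and Crebl2 and for the described lists, 166 gene results and 79 list results lost the threshold, 22 and 12 gained it, 16 and 16 changed sign, and 2408 and 553 stayed. The shallow libraries limit low genes most.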

Other observations

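Families of genes that share the letters of their symbol were compared by camera after seeing the data, 145 families in all, and each call was lost with an estimated correlation (adjusted p = 0.994). Of 15 Mup genes, which encode major urinary proteins, 10 rose, and 5 did under a common median (camera adjusted p = 0.000584). Of 18 Ugt genes, which encode glucuronosyltransferases, 12 rose, and 6 did under a common median (camera adjusted p = 0.000584). Of 53 genes with Eif symbols, most of which encode translation initiation factors, 35 rose, and 5 did under a common median, while 1 fell, the repressor gene Eif4ebp3 (camera adjusted p = 0.00134). Of 28 Polr genes, which encode RNA polymerase subunits, 16 rose, and 3 did under a common median (camera adjusted p = 0.00737). Serpina genes fell in 4 of 16 cases and in 5 under a common median, and 1 rose (camera adjusted p = 0.00617). The families given so far are a selection of those past camera. Among the others, Rpl, Rps and Lsm genes lay above other genes (camera adjusted p = 8.6e-07, 5.33e-05 and 0.0442). Hist, Clec, Rgs and Aldh genes lay below them (camera adjusted p = 5.33e-05, 0.000582, 0.00575 and 0.00617). Il, Slc and C genes did too (camera adjusted p = 0.0137, 0.0152 and 0.0158). So did the collagen family, Col (camera adjusted p = 0.0355). Of 21 Col genes, 3 rose and 1 fell, or 0 and 2 under a common median.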
